A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

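Newly made RNA of Saccharomyces cerevisiae was measured on 22 spotted arrays with a pair of dyes each. Cells had received 5 mM 4-thiouracil (4tU), a uracil analog that enters RNA as it is transcribed, shortly before harvest, and the labelled fraction was pulled out, amplified and dyed. Per the labels, both strains carry the anchor-away background: a tor1-1 allele and a deleted FPR1, which remove the usual response to rapamycin, and RPL13A fused to FKBP12. In Hsf1-aa the transcription factor Hsf1 also carries an FRB-yEGFP tag, so that rapamycin ties it to ribosomal proteins, which carry it out of the nucleus. WT-aa has the same background without the tag. The slow time course (20 arrays) sampled both strains at 0, 15, 30, 60 and 90 min of 0.15 µM rapamycin, with 2 arrays per strain and time (letters a and b). The standard depletion (2 arrays) sampled each strain once at 30 min of 7.5 µM rapamycin.

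Each slow array set the sample against a pool of 4tU RNA from untreated WT-aa cells. The sample was in Cy3 on every array of letter a and in Cy5 on every array of letter b, so letter and dye are the same factor and are balanced over the 10 groups. The series states that the 2 arrays of a group came from independent cultures. The array titles carry the same running number for both letters, and its meaning is not given in the sources used here. If the letters were dye swaps of 1 culture, the standard errors and p-values would cover technical spread alone. No pairing of a WT-aa culture with an Hsf1-aa culture is stated, and the letter entered the fit only as the dye. The standard arrays had the sample in Cy5 and an unlabelled reference, so only their strain difference was compared with the slow course.

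The scanner files deposited by the authors hold a linear intensity per spot for each dye, with the local background in separate columns and nothing subtracted, per the file headers. The scanner and image software are not given in the sources used here. A further deposited table holds the log2 ratio of Cy5 to Cy3 as processed by the authors. Its normalization is not given in the sources used here, and its column medians lay between -0.00704 and 0.0224. Over the yeast spots its columns correlated at r = 0.631 to 0.971 with the scanner ratios as background-corrected and normalised below. It was used as an alternative.

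Each array held 15552 spots: 12776 yeast spots (6388 probes spotted 2 times each), 1872 spots for external control RNA added during amplification, and 904 quality control spots. Of the yeast probes, 5326 had a gene symbol and 1062 had none, and the latter were tested under their probe names. Out-of-date symbols (58) were brought up to date through synonyms. Spot intensity (Signal Mean over Background Median) was background-corrected by normexp with an offset of 50 and normalised by loess within each array, with control spots given weight 0. Ratios were turned to sample over reference, and the spots of a gene were averaged on the log2 scale. A gene was tested if at least 1 of its spots lay above the background median by 2 background SD in the sample channel on at least 2 of the 20 slow arrays, which left 6353 features, of which 5293 were named genes. Loess sets the middle of each array to 0, so a change shared by all genes cannot be seen. Median sample foreground was 863.5 to 1789 units over a median background of 42 to 56 units. Signal over background in the sample channel was 19.1 to 38.1 on the slow arrays and 17.0 to 17.4 on the standard arrays. The reference channel of the standard arrays was dim, with a median foreground of 172.6 (Hsf1-aa) and 297 (WT-aa) units. On the slow arrays it was 759.9 units or more. The number of arrays limits the precision.

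All 20 slow arrays were fitted together in limma 3.58.1 (R 4.3.3; lmFit and eBayes), with 10 groups and a term for the dye, which left 9 residual degrees of freedom and 12.55 with the prior. The contrasts were Hsf1-aa minus WT-aa at each time and the change of that difference from 0 min (the interaction). Within each strain they were 90 against 0 min and a moderated F-test of the 4 later times against 0 min. Counts of features changing over time and the choice of time-course genes used the F-test. Adjusted p-values of single genes and list members within a strain are those of 90 against 0 min, unless stated. Whether an alternative kept such a gene's call was judged by the F-test. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over all features of a contrast, with a threshold of 0.05. Standard errors are those of this fit, with 1 spread per gene over all groups. Array quality weights were 0.449 and 0.442 at 30 min (Hsf1-aa and WT-aa) and 1.62 and 1.51 at 0 min. P-values may thus be too large at 0 min and too small at 30 min. Of 6353 features, 106 at 0 min, 869 at 30 min and 252 at 90 min had an unadjusted p under 0.05. The counts at 0 and 90 min lie below the share of 0.05 that no difference would give.

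The comparisons, the genes to be named and 29 gene lists were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists of a contrast, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. The genes named were the 10 largest falls and 10 largest rises of each strain contrast among those past the threshold with the same sign on both letters; the 5 largest of each for the interaction and the time courses; the 4 largest changes of any list that passed camera; HSF1 and the other genes used to build the strains; any Hsf1 chaperone target; and the 5 largest of each direction for the standard pair. Unnamed probes were outside this rule, and those named were chosen after their values were seen. The standard pair has 1 array per strain and no test; its list medians were set against 10000 random lists of the same size matched on intensity.

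The array directions were taken from the labels. A check against the dye effect estimated from arrays of the other times put 20 of 20 arrays on the side their label gives. It cannot reveal a wrong label, since each ratio had been turned by its label before the check. Among 90 pairs of arrays with the same dye orientation, 2 correlated below -0.3 (lowest r = -0.388, WT-aa 0 min replicate a with WT-aa 30 min replicate a). The fit was tested on simulated data with the same design: changes of 0.5, 1 and 2 log2 units between strains were found in 77.6%, 97.5% and 100% of cases, with 5.27% false calls, none of the wrong sign and 0 calls in a comparison without changes. For the interaction the shares were 50.1%, 92.1% and 99.4%. Camera found 10 of 10 lists shifted by 0.3 and 0 lists without a shift. The simulated noise was independent between genes and arrays, with 1 spread per gene over all groups. In the real data 1 axis held 53.1% of the residual variance, so these shares and false calls may not carry over.

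The alternatives were no dye term, a dye term per strain, no background correction, median centring, print-tip loess, centring on the external control RNA, equal scale between arrays, the authors' processed values, no filter on dim genes, a filter to features detected on all 20 arrays, an intensity trend with a robust prior, an added threshold of 1.7-fold, and leaving out each array in turn. Array quality weights and camera on the interaction contrasts, also under each scaling, were added after seeing the data. A model with slide or scan batches was not run, since the files give none. FPR1 and SSA2 had no probe with their symbol and have no values.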

Results

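Hsf1 is the transcription factor that drives chaperone genes in budding yeast, both in growing cells and after heat. The arrays followed newly made, 4tU-labelled RNA while Hsf1 was removed from the nucleus, slowly over 90 min at 0.15 µM rapamycin or within 30 min at 7.5 µM. The slow course had 2 arrays for each of 2 strains (Hsf1-aa and WT-aa) at each of 5 times. The standard depletion had 1 array per strain. Between 6282 and 6351 features were detected on the slow arrays and 6169 and 6215 on the standard ones. Values are log2 differences between strains (Hsf1-aa minus WT-aa) unless stated otherwise, followed by the SE of the limma fit, with n = 2 arrays per group. The replicate arrays of a group correlated at r = -0.208 to 0.736 across genes (median 0.237). HSF1 itself (YGL073W, on chromosome VII) was read by 1 probe and detected on all 20 slow arrays. No genome build is named in the sources, so positions are not given.

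The 0 min arrays asked how the tagged strain differed before rapamycin. HSF1 gave a lower signal in Hsf1-aa, at -2.17 ± 0.23 (adjusted p = 9.71e-04; 4.51-fold). TIS11, which encodes an RNA-binding protein that speeds the decay of mRNAs for iron-using proteins, was lower at -0.67 ± 0.11 (adjusted p = 0.0398). The uncharacterised YCR001W was higher by 0.74 ± 0.09, CIT2 (peroxisomal citrate synthase) by 0.46 ± 0.08 and FRM2 (a nitroreductase-like protein) by 0.41 ± 0.07. HSF1 stayed lower at the 4 later times, at -2.23, -2.04, -1.53 and -1.63. The 18 measured Hsf1 chaperone targets had a median of -0.07, and 0 of them passed, also when adjusted over the list alone. Of all 6353 features 106 had an unadjusted p under 0.05, below the share of 0.05 that no difference would give. The p-values at 0 min may thus be too large, so a missing call there says little. Iron regulon genes, which take up and share out iron, lay lower (20 measured, median -0.17; 20 below 0; 1 past the threshold and 5 adjusted over the list alone; adjusted p = 0.0395 with an estimated correlation). Other heat-shock-inducible genes had a median of -0.11, with 0 of 17 past the threshold and 1 adjusted over the list alone (adjusted p = 0.0485 with an estimated correlation). Yap1 oxidative stress genes had a median of 0.17, with 0 of 16 past the threshold and 1 adjusted over the list alone (adjusted p = 0.0395), and phosphate regulon genes one of 0.07, with 0 of 15 (adjusted p = 0.0485); centring on the external control RNA turned both of these to -0.027 and -0.094, where the median of all genes was -0.173. The other genes used to build the strains, such as TOR1 and RPL13A, did not differ (adjusted p = 0.998). In all, 8 features passed, 4 higher and 4 lower. Leaving out an array at a time gave 4 to 8 (4 or 5 for 14 of the 20 arrays), and centring on the external control RNA gave 2. The calls of CIT2 and FRM2 held under 9 of 33 alternatives each, and that of TIS11 under 15.

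At 15 min of rapamycin a few chaperone genes were lower in Hsf1-aa, while 0 features had a strain difference that had changed from 0 min. At 0 min CPR6 and APJ1 had been at -0.20 each and FES1 at -0.02. CPR6, a cyclophilin that works with Hsp90, was lower at -0.69 ± 0.12 (adjusted p = 0.0345), APJ1, a J-domain co-chaperone, at -0.62 ± 0.09 (adjusted p = 0.00757), and FES1, a nucleotide exchange factor of Hsp70, at -0.44 ± 0.07 (adjusted p = 0.015). TIP1, a cell wall mannoprotein, was lower at -0.70, RTS3, a putative phosphatase component, at -0.66, HSP30, a plasma membrane stress protein, at -0.61, ERO1, the oxidase of disulfide formation in the ER, at -0.58, UBC4, a ubiquitin-conjugating enzyme, at -0.43 and AGP1, an amino acid permease, at -0.38. CYC7, a cytochrome c isoform, was higher by 0.40 ± 0.05. Of the 18 Hsf1 chaperone targets, 3 were lower, or 8 adjusted over the list alone, and their median was -0.30 (adjusted p = 0.183 with an estimated correlation). TIP1, HSP30 and ERO1 made 3 of 17 for the other heat-shock-inducible genes (10 lower and 2 higher adjusted over the list alone; median -0.19; adjusted p = 0.183 with an estimated correlation). The general stress genes driven by Msn2 and Msn4 had a median of 0.23 with 0 past the threshold (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.312 with an estimated correlation). In all, 14 features passed, 12 lower and 2 higher. The count was 4 without Hsf1-aa 15 min replicate b, 6 without its replicate a, 8 or 9 without WT-aa 15 min replicate b or any WT-aa array of 0, 60 or 90 min, and 2 with centring on the external control RNA. ERO1 and UBC4 kept their calls under 12 of 33 alternatives each, AGP1 under 14, HSP30 under 15 and RTS3 under 16.

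At 30 min most Hsf1 chaperone targets were lower in Hsf1-aa. BTN2, which directs misfolded proteins to storage sites, was lower at -1.71 ± 0.09 (adjusted p = 1.18e-06), HSP42, a small heat-shock protein, at -1.34 ± 0.12, and CUR1, a sorting factor related to BTN2, at -1.04 ± 0.12. RTS3 was lower at -1.11, HSP78, the mitochondrial disaggregase, at -0.85, HSP30 at -0.83, and FES1 and APJ1 at -0.81 each, and CPR6 was 2.01-fold lower. YCR001W was higher by 0.69 ± 0.09, PHO84, a phosphate transporter, by 0.60 ± 0.11 and ARG3, an enzyme of arginine synthesis, by 0.35 ± 0.06. Of the 18 Hsf1 chaperone targets, 12 were lower and 16 adjusted over the list alone, with a median of -0.75 (1.68-fold; adjusted p = 0.0209 with an estimated correlation). SSA1, a cytosolic Hsp70, had the smallest difference of them, -0.31 ± 0.23 (adjusted p = 0.457). Other heat-shock-inducible genes were lower in 8 of 17 members (10 adjusted over the list alone; median -0.51; adjusted p = 0.0287 with an estimated correlation), with SSE1, an Hsp110 chaperone, at -0.80 and HSP26, a small heat-shock protein, at -0.63. Glycolysis genes were lower in 3 of 16 members, PGK1 (-0.74), ENO2 (-0.44) and GPM1 (-0.39), and in 4 adjusted over the list alone (median -0.13; adjusted p = 0.147 with an estimated correlation). Among the Pdr1 drug resistance genes PDR15, a drug pump, was lower at -0.58 (1 of 13, 2 adjusted over the list alone; median -0.12; adjusted p = 0.274 with an estimated correlation). In all, 50 features passed, 46 lower and 4 higher, of which 12 lower ones were Hsf1 chaperone targets and 6 were unnamed probes. The count was 940 without Hsf1-aa 30 min replicate b, 126 without WT-aa 30 min replicate b, 32 without WT-aa 30 min replicate a and 5 with centring on the external control RNA.

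At 60 min nearly every Hsf1 chaperone target was lower in Hsf1-aa. BTN2 was lower at -2.57 ± 0.09 (5.95-fold; adjusted p = 8.05e-09), HSP42 at -2.36 ± 0.12 and CUR1 at -2.06 ± 0.12. The Hsp90 genes HSP82 and HSC82 were lower at -1.87 and -1.71, HSP104, the cytosolic disaggregase, at -1.73, the J-domain protein SIS1 at -1.69, HSP78 at -1.83, CPR6 at -1.74 and the Hsp90 activator AHA1 at -1.54. Of the 18 targets, 17 passed and 18 did adjusted over the list alone, and the median was -1.61 (3.06-fold; adjusted p = 0.0027 with an estimated correlation). YDJ1, another J-domain protein, missed the threshold at -1.05 ± 0.23 (adjusted p = 0.051). Other heat-shock-inducible genes were lower in 9 of 17 members (12 lower and 2 higher adjusted over the list alone; median -0.60; adjusted p = 0.0169 with an estimated correlation), among them SSE1 at -1.03, HSP26 at -0.80 and RPN4, the activator of proteasome genes, at -0.77. Most of the 10 largest rises were in iron genes: TIS11 was higher by 0.99 ± 0.11 (adjusted p = 1.61e-04), FET3 and FTR1, which form the high-affinity iron uptake complex, by 0.68 and 0.60, MRS4, a mitochondrial iron carrier, by 0.52, ENB1, a siderophore transporter, by 0.52, CCC2, which supplies copper to Fet3, by 0.39, and FRE1, a metal reductase, by 0.37. CIN5, a stress transcription factor (0.65), GTO3, a glutathione transferase (0.59), and VMR1, a vacuolar transporter (0.50), were also higher. In the iron regulon 7 of 20 members were higher and 1 lower (10 and 1 adjusted over the list alone; median 0.23; adjusted p = 0.2275 with an estimated correlation). Ribosomal protein genes had a median of -0.15 with 0 of 120 past the threshold (0 adjusted over the list alone; adjusted p = 0.2275 with an estimated correlation). In all, 77 features passed, 65 lower and 12 higher. Of the lower ones 43 were also lower at 30 min, where 0.47 would be shared if the calls were independent. They are not, since all contrasts share the spread of 1 fit, so the overlap is no replication. The count was 143 without either Hsf1-aa 30 min replicate, 44 and 50 without Hsf1-aa 60 min replicates a and b, 45 and 49 without WT-aa 60 min replicates a and b, and 25 with centring on the external control RNA (1 higher), which ended the calls of the 10 rises named. CIN5 kept its call under 14 of 33 alternatives and MRS4 under 16.

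At 90 min all 18 Hsf1 chaperone targets were lower in Hsf1-aa, with a median of -2.13 (4.36-fold; adjusted p = 3.13e-05 with an estimated correlation). HSP82 was lower at -2.98 ± 0.15 (7.91-fold; adjusted p = 5.09e-08), BTN2 at -2.95 ± 0.09 and HSC82 at -2.70 ± 0.09. SIS1 was lower at -2.55, HSP104 at -2.51, CUR1 at -2.47, HSP42 at -2.44, STI1, which links Hsp70 to Hsp90, at -2.28, HSP78 at -2.13 and SSA1 at -2.12. HCH1, an Hsp90 regulator, had the smallest difference of the 18 at -1.08. The 18 were also lower adjusted over the list alone. Other heat-shock-inducible genes were lower in 9 of 17 members (12 adjusted over the list alone; median -0.62; adjusted p = 3.09e-04 with an estimated correlation), led by SSE1 at -1.43, RPN4 at -0.97, SSE2 (a second Hsp110) at -0.91 and SSA4 (an inducible Hsp70) at -0.85. Of 20 genes of mitochondrial chaperones and import, 4 were lower, both over all genes and adjusted over the list alone. These were the chaperonin genes HSP60 (-1.23) and HSP10 (-1.03) and the Hsp70 genes SSC1 (-0.91) and ECM10 (-0.53), while the median was -0.051 (adjusted p = 0.0138 with an estimated correlation) and turned to 0.014 with centring on the external control RNA, where that of all genes was 0.0497. All 33 proteasome genes lay below 0 (median -0.097), but only RPN4 passed, also adjusted over the list alone (adjusted p = 0.0802 with an estimated correlation).

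Iron regulon genes made 7 of the 13 features that were higher at 90 min. TIS11 was higher by 1.08 ± 0.11 (2.11-fold; adjusted p = 5.99e-05), FET3 by 0.72, FIT2, a cell wall protein that retains siderophores, by 0.65, FRE1 by 0.57, ENB1 by 0.57, FRE4, a siderophore reductase, by 0.37 and CCC2 by 0.37. CTH1, which is related to TIS11, was lower (fold 1.64; adjusted p = 4.68e-04). The iron regulon had 7 members higher and 1 lower (12 and 1 adjusted over the list alone; median 0.36; adjusted p = 0.005 with an estimated correlation). VMR1 (0.49), YCR001W (0.43) and the uncharacterised YMR187C (0.35) completed the 10 largest rises. PGK1 was lower at -0.68 and GPM1 also passed, 2 of 16 glycolysis genes and 4 adjusted over the list alone (adjusted p = 0.176 with an estimated correlation). Genes of folding in the ER had 1 member higher and 2 lower (2 and 2 adjusted over the list alone) and a median of 0.055 but a mean of -0.021, and camera gave no call (adjusted p = 0.242). In all, 78 features passed, 65 lower and 13 higher. Of the lower ones 18 were Hsf1 chaperone targets, 9 were unnamed probes and 52 were also lower at 60 min (0.67 if independent, which they are not). Centring on the external control RNA gave 24, of which 17 were targets and 1 was higher, and ended the calls of the 7 iron genes that were higher (TIS11 at 1.13, adjusted p = 0.0751). Leaving out an array at a time gave 58 to 81. FIT2 kept its call under 13 of 33 alternatives.

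**Figure D1:**
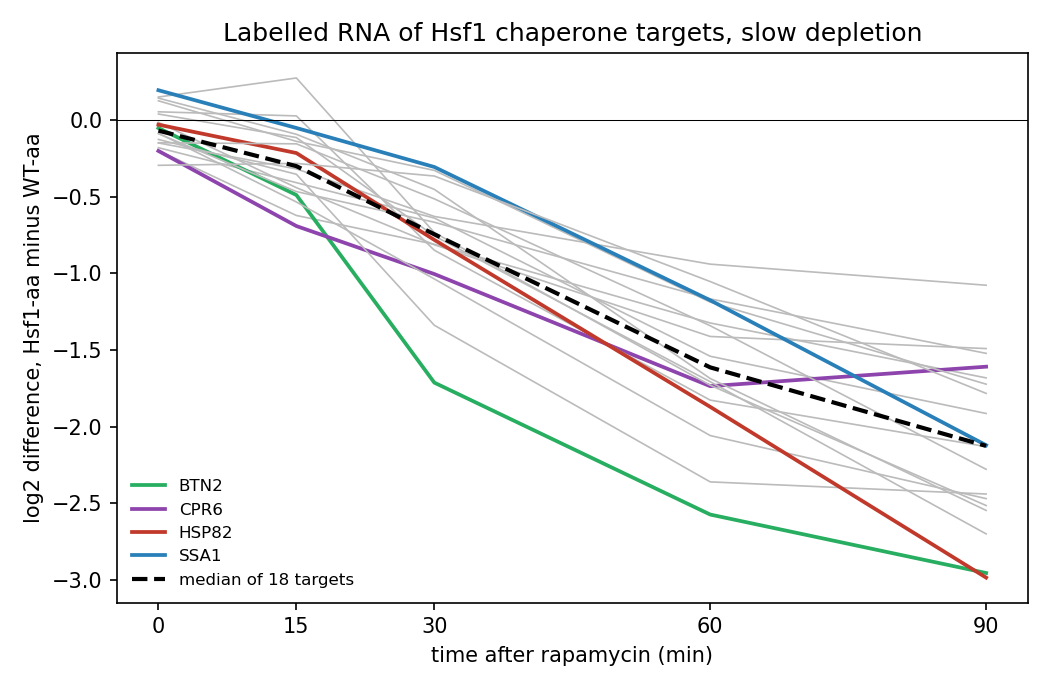
Log2 difference of labelled RNA (Hsf1-aa minus WT-aa, y axis) against minutes after 0.15 µM rapamycin (x axis), with a line for each of the 18 Hsf1 chaperone targets and a dashed line for their median. The median runs from -0.07 at 0 min to -2.13 at 90 min.

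The interaction asked whether the strain difference itself had changed from 0 min, which removes differences present before rapamycin. By 30 min the changes were -1.66 ± 0.13 for BTN2, -1.21 for HSP42, -0.80 for FES1, -0.79 for HSC82 and -0.73 for SSC1, the mitochondrial Hsp70, against 0.93 for TIS11. By 60 min the changes were -2.52 for BTN2, -2.23 for HSP42, -1.97 for CUR1 and -1.88 each for HSP78 and HSP104, against 1.66 for TIS11, 0.88 for FTR1, 0.85 for GTO3, 0.78 for ENB1 and 0.73 for VMR1. By 90 min they were -2.95 ± 0.21 for HSP82 (adjusted p = 4.69e-06), -2.90 for BTN2, -2.74 for HSC82, -2.69 for SIS1 and -2.66 for HSP104, against 1.75 ± 0.16 for TIS11 (adjusted p = 3.78e-05), 0.98 for ARN1, a siderophore transporter, 0.83 for ENB1, 0.82 for FTR1 and 0.77 for FRE1. Most of the 33 alternatives ended the calls of HSC82 (kept under 12) and TIS11 (13) by 30 min, FTR1 (14) and GTO3 (15) by 60 min, and FTR1 (12) and ARN1 (14) by 90 min. In limma 0 features passed by 15 min, where 232 had an unadjusted p under 0.05, also below a share of 0.05 of the 6353 tested. By 30 min 7 passed, by 60 min 42 (34 falls and 8 rises) and by 90 min 48 (39 and 9). With centring on the external control RNA the 3 later counts were 0, 6 and 13. The count by 30 min was 566 without Hsf1-aa 30 min replicate b and 2 without Hsf1-aa 0 min replicate a, and that by 60 min was 24 or 27 without an array of 0 min.

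Within Hsf1-aa, RNA of the chaperone genes fell from 0 to 90 min: BTN2 at -3.26 ± 0.09, HSP82 at -3.10 ± 0.15, HSC82 at -2.89, HSP104 at -2.87 and SIS1 at -2.80. All 18 Hsf1 chaperone targets fell (median -2.24; also 18 adjusted over the list alone; adjusted p = 0.00168 with an estimated correlation). In WT-aa, where no Hsf1 tag is present, their median was -0.14 and 0 of 18 fell, or 2 adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). BIO5, a transporter, rose by 1.67 ± 0.10 in Hsf1-aa and 1.59 ± 0.10 in WT-aa, BIO3 by 1.35 and 1.21, and BIO4 by 1.22 and 1.05, the last 2 being enzymes of biotin synthesis. The zinc transporter ZRT1 rose by 0.74 in Hsf1-aa and 1.23 in WT-aa, a difference of -0.49 that passed (adjusted p = 0.0353). CIT2 rose by 0.66 and 1.11. The uncharacterised YJR154W rose by 2.17 ± 0.47 in Hsf1-aa (adjusted p = 0.0264 for 90 against 0 min and 0.0403 for the F-test). Its F-test call was kept under 15 of 33 alternatives. In WT-aa it was at 1.65 ± 0.47 (adjusted p = 0.217 for 90 against 0 min). The change of its strain difference, 0.52 ± 0.67, did not pass, and its wide SE leaves a difference open. NCE103, a carbonic anhydrase, fell at -1.33 and -1.30.

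Genes of the response to oxidants mediated by Yap1 fell in both strains, with FLR1, a drug transporter, at -1.63 in Hsf1-aa and -1.08 in WT-aa and OYE3, an NADPH oxidoreductase, at -1.35 and -1.03. In Hsf1-aa 5 of 16 members fell (9 adjusted over the list alone; median -0.34; adjusted p = 0.0225 with an estimated correlation), and in WT-aa 3 (7 adjusted over the list alone; median -0.22; adjusted p = 0.0159). Of the Pdr1 drug resistance genes 4 of 13 fell in Hsf1-aa (6 adjusted over the list alone; median -0.19; adjusted p = 0.0234 with an estimated correlation), among them the drug pump PDR5 (-0.89) and the polyamine transporter TPO1 (-0.82), and 0 in WT-aa, also adjusted over the list alone (median -0.16; adjusted p = 0.0293). Iron genes fell in WT-aa, where FRE4 was at -1.44 ± 0.06, TIS11 at -1.27, FIT2 at -1.14 (fold 2.2) and ARN1 at -1.02. There 8 of 20 iron regulon genes fell (15 adjusted over the list alone; median -0.51; adjusted p = 0.00205 with an estimated correlation), while in Hsf1-aa TIS11 rose by 0.48 ± 0.11, 2 fell, the same counts held adjusted over the list alone, and the median was 0.0022 (adjusted p = 0.9475 with an estimated correlation).

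**Figure D2:**
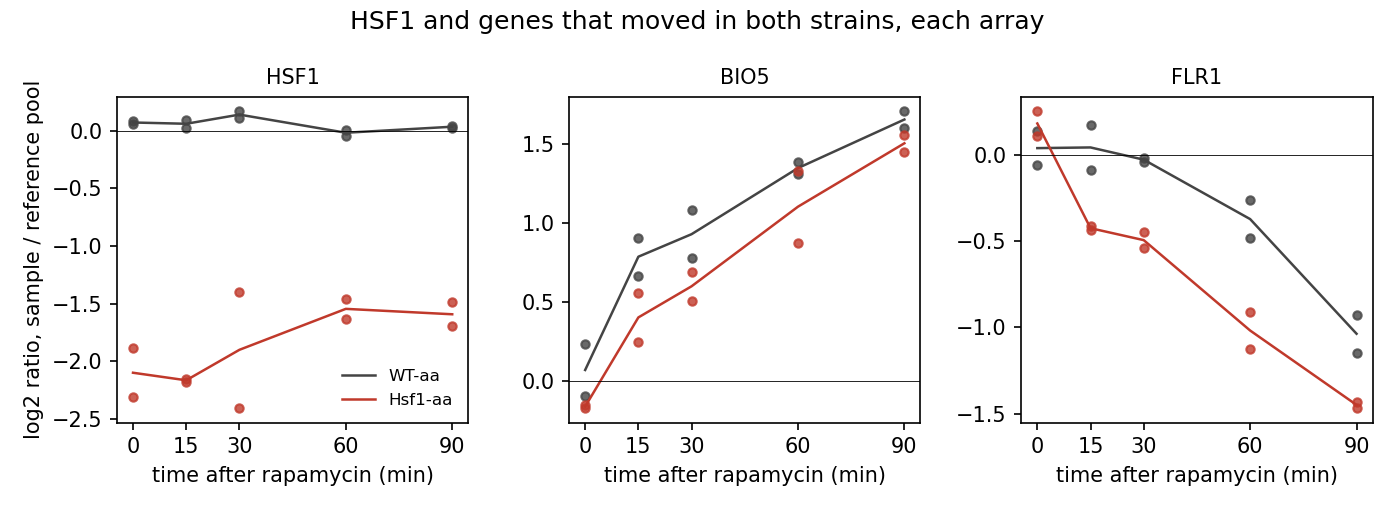
Log2 ratio of the sample to the reference pool (y axis) against minutes after 0.15 µM rapamycin (x axis) for HSF1, BIO5 and FLR1 in both strains, with a point per array and a line through the mean of the 2 arrays of each group. HSF1 lies lower in Hsf1-aa than in WT-aa at every time, while BIO5 rose in both strains, by 1.67 and 1.59 at 90 min.

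**Figure D3:**
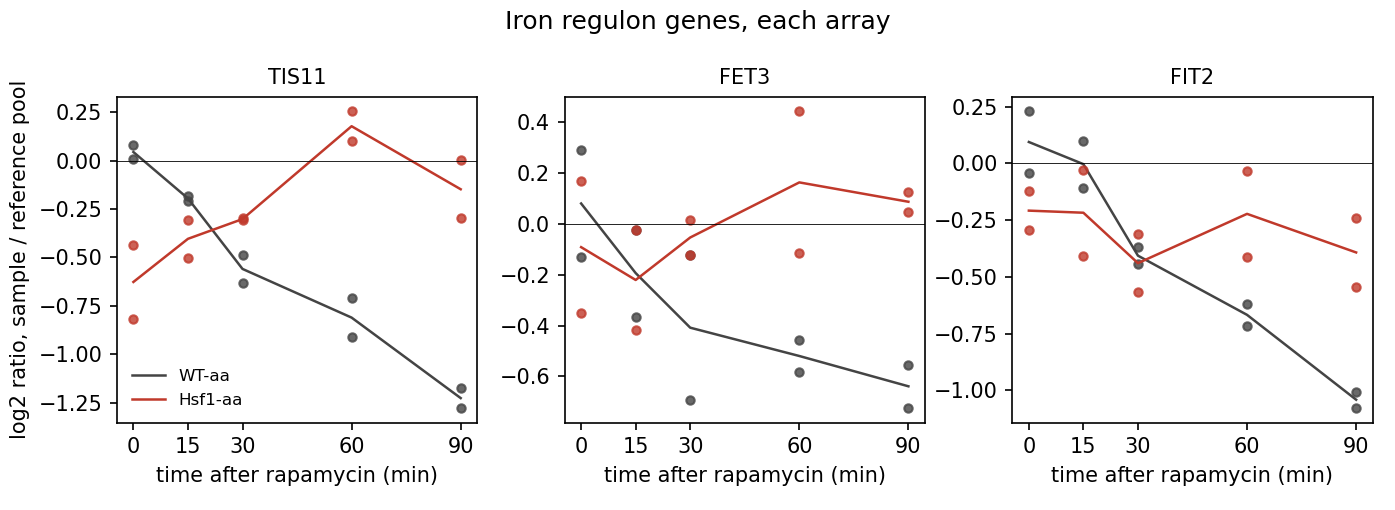
Log2 ratio of the sample to the reference pool (y axis) against minutes after 0.15 µM rapamycin (x axis) for TIS11, FET3 and FIT2 in both strains, with a point per array and a line through the mean of the 2 arrays of each group. TIS11 fell by 1.27 in WT-aa and rose by 0.48 in Hsf1-aa from 0 to 90 min.

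Smaller shifts marked the cell cycle and mating lists. G1/S genes rose in Hsf1-aa (3 of 15, among them MCD1, a cohesin subunit, at 0.47 and the cyclin PCL1 at 0.42; 6 adjusted over the list alone; median 0.21; adjusted p = 0.0225 with an estimated correlation), and in WT-aa had a median of 0.13 with 0 past the threshold and 4 adjusted over the list alone (adjusted p = 0.0102). In WT-aa, mating-induced genes rose in 3 of 15 members, PRM6 (0.60), AGA1 (0.38) and FIG1 (0.33), and in 7 adjusted over the list alone (median 0.20; adjusted p = 0.00205 with an estimated correlation). Sulfur genes of WT-aa rose in 2 of 19 members, STR3 (0.54) and MET17 (0.39), and in 4 adjusted over the list alone (median 0.088; adjusted p = 0.0102 with an estimated correlation), and the 4 MATalpha-specific genes had a median of 0.29 with 0 past the threshold and 3 adjusted over the list alone (adjusted p = 0.0307). Of the MATalpha-specific genes, MF(ALPHA)1 had 1 spot near the scanner limit on WT-aa 90 min replicate b. Centring on the external control RNA turned the WT-aa medians of these lists to -0.11 (G1/S), -0.054 (mating), -0.077 (sulfur) and -0.042 (MATalpha). That centring took the median of all genes in WT-aa at 90 min to -0.231. Over the whole course 298 features changed in Hsf1-aa (114 higher and 184 lower at 90 min) and 85 in WT-aa (42 and 43). Of these 69 changed in both strains, where 3.99 would if the calls were independent, which they are not. Of the 69, 61 had the same direction at 90 min. Without WT-aa 30 min replicate b the WT-aa count was 1218, without either Hsf1-aa 30 min replicate it was 665, without WT-aa 15 min replicate b or any WT-aa array of 0, 60 or 90 min it was 38 to 56, and with centring on the external control RNA it was 0; the Hsf1-aa count was 771 and 672 without Hsf1-aa 30 min replicates a and b, 183 and 148 without Hsf1-aa 15 min replicates a and b, 194 without Hsf1-aa 60 min replicate a and 32 with that centring.

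The standard depletion, at 7.5 µM rapamycin for 30 min, asked what a faster loss of Hsf1 gave, without a test, since it had 1 array per strain. HSP82 was lower in Hsf1-aa at -3.69 (12.9-fold), SSA1 at -3.36, HSC82 at -3.26, SIS1 at -3.09 and MBF1, a transcriptional coactivator, at -2.91. These were the 5 largest falls. All 18 Hsf1 chaperone targets lay below 0 (median -1.82), and 10000 random lists had medians between -0.158 and 0.125. Random lists lack the shared regulation of a real list, so a place among them describes these 2 arrays and tests no strain difference. The dim reference channel differed between the 2 arrays (172.6 units in Hsf1-aa and 297 in WT-aa). Whether it cancels in the small list medians was not tested. BTN2 was at -2.57 and APJ1, the smallest of the 18, at -0.44. HSF1 was at -1.32. The 5 largest rises were TRX1, a thioredoxin (0.93), POC4, a proteasome assembly factor (0.92), YJL068C, a formylglutathione hydrolase (0.79), SPS19, an enzyme of fatty acid oxidation (0.78) and FUN26, a nucleoside transporter (0.74). General stress genes had a median of 0.24 (above all random lists; 2 of 29 below 0) and genes of folding in the ER one of 0.15 (above all random lists). Proteasome genes were at -0.15 (below all random lists, 32 of 33 below 0) and the iron regulon at -0.10 (percentile 0.01, 17 of 21 below 0). Ribosomal protein genes were at -0.069 (below all random lists, 89 of 120 below 0) and other heat-shock-inducible genes at -0.11 (percentile 0.04). Cell wall integrity genes (0.13, percentile 99.95) and genes of pyrimidine and uracil salvage (0.13, percentile 99.92) lay near the top.

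Slow and standard depletion differ in dose, time and reference, so their strain differences stand side by side. Of the 18 Hsf1 chaperone targets 17 fell more in the standard pair than at 15 min of the slow course, 17 more than at 30 min, 10 more than at 60 min and 5 more than at 90 min. Across 6134 genes, which are not independent replicates, the strain differences of the standard pair correlated with those of the slow course at Pearson r = -0.033, 0.178, 0.298, 0.42 and 0.603 from 0 to 90 min, and at Spearman rho = -0.147, 0.126, 0.193, 0.220 and 0.179. Without the 18 targets Pearson r at 90 min was 0.336.

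**Figure D4:**
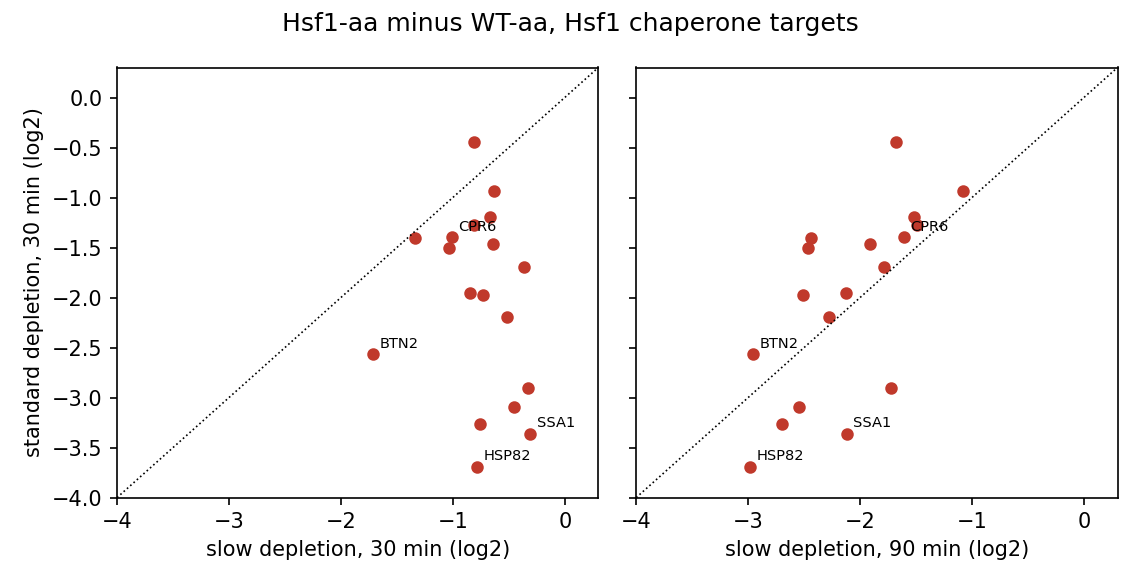
Log2 difference (Hsf1-aa minus WT-aa) of the 18 Hsf1 chaperone targets in the standard pair at 30 min (y axis) against slow depletion (x axis, panels for 30 and 90 min), with a point per gene and a dotted line where both are equal. Against 30 min of slow depletion 17 of the 18 points lie below the line, and against 90 min 5 do.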

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

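The tests of lists on the interaction (also under other scalings), of the Hsf1 chaperone targets at 0 min and of a drift of iron genes shared by both strains were chosen after the result was seen; the others were chosen before.

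The strain difference itself changed with time, which is what brought the following to attention. Against 0 min, 7 features had a changed difference at 30 min, 42 at 60 min and 48 at 90 min. The Hsf1 chaperone targets had a median change of the strain difference of -1.46 by 60 min (adjusted p = 0.0061 with an estimated correlation) and of -2.16 by 90 min (adjusted p = 3.71e-05). By 90 min the other heat-shock-inducible genes had changed by -0.355 (adjusted p = 0.00227 with an estimated correlation) and the mitochondrial chaperones and import genes by -0.0769 (adjusted p = 0.0232). The iron regulon changed by 0.491 (adjusted p = 0.00211 with an estimated correlation) and the mating-induced genes by -0.142 (adjusted p = 0.0368), with 0 mating-induced genes past the threshold themselves. Centring on the external control RNA moved the median of all genes from -0.00585 to 0.227 for this change by 90 min. It turned the mating-induced median to 0.097 and the mitochondrial one to 0.17, both still below that of all genes, and gave -0.186 for the other heat-shock-inducible genes and 0.725 for the iron regulon. Under it these 4 lists had no call (adjusted p = 0.369 for the other heat-shock-inducible genes, 0.311 for the iron regulon and 0.995 for the other 2, with an estimated correlation), while the targets kept theirs (-1.36 by 60 min and -1.87 by 90 min). Median centring ended the calls of the mitochondrial (adjusted p = 0.0827) and mating-induced genes (adjusted p = 0.0763), and equal scale that of the targets by 60 min (-1.21; adjusted p = 0.363).

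Iron genes parted between the strains: from 0 to 90 min 8 of 20 fell in WT-aa, while in Hsf1-aa 2 fell and 1 rose. A single unusual array is excluded, since leaving out each of the 8 arrays at 0 and 90 min kept the median at 0.427 or more. A drift of iron supply common to both cultures, acting alike on both strains, would keep the order in which the strains started. The median strain difference was -0.171 at 0 min (20 of 20 genes below 0, adjusted p = 0.0395 with an estimated correlation, 0.0646 with fry). At 90 min it was 0.361 (adjusted p = 0.005 and 0.00101). The crossing argues against such a drift as the whole cause, by a rule set after the values were seen. A shared drift to which the strains responded unequally stays open. A difference between the cultures of the 2 strains that is not due to Hsf1, such as their medium or day, cannot be told apart from the strain, since the labels give no batches. An effect of Hsf1 loss itself was not tested apart from the strain, and the standard pair, which has no 0 min arrays of its own, had the iron regulon at -0.10 (17 of 21 below 0).

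HSF1 gave a lower signal in Hsf1-aa before rapamycin and at each later time. Lower Hsf1 activity before rapamycin stays open: the 18 chaperone targets had a median of -0.07 at 0 min (95% bootstrap interval over genes -0.15 to 0.0453), above a bound of -0.30 set after the values were seen, but the other heat-shock-inducible genes lay lower (median -0.11, 13 of 17 below 0; adjusted p = 0.0485 with an estimated correlation). The tag at the 3' end of the gene may have changed what the probe reports: the standard pair, with another reference, had HSF1 at -1.32, as this explanation needs. Lower transcription of the tagged gene would give the same value, so the 2 cannot be told apart here.

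Arrays varied along an axis that neither group nor dye explained. It held 53.1% of the residual variance, against 17.5% for the next. Hsf1-aa 30 min replicates a and b lay at its ends (0.451 and -0.451), and WT-aa 30 min replicates a and b came next (-0.394 and 0.394). With 2 arrays per group and a dye term, a and b mirror each other in every group by construction. Carry-over of unlabelled RNA into the 4tU fraction stays open. The loadings of 6134 genes did not follow the ratio of labelled to unlabelled RNA (rho = -0.0333). That ratio was available only from the standard arrays, whose reference channel was dim (median 172.6 units in Hsf1-aa and 297 in WT-aa). Noise in the ratio would weaken any correlation, so this rho cannot decide the question. A bias by gene length is excluded as the main source (rho = -0.0377). Growth state stays open: ribosomal protein and ribosome biogenesis genes together lay at percentile 16 of random lists, which was to count against it, but that bound was wrong, since the 2 groups had loadings of opposite sign (-0.00596 and 0.00653) that cancel.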

How the results depend on the processing

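Array quality weights were chosen after the result was seen; the other alternatives were chosen before. For 133 values of named genes (all calls except YDJ1 at 60 min) and 68 list calls, 0 gene values and 19 list medians reversed. This was over 33 alternatives for genes and 33 for lists. Alternatives that change only the test, such as fry or the 1.7-fold threshold, keep the estimate, so nothing could reverse under them. The 18 Hsf1 chaperone targets were all called at 90 min in every alternative fit except centring on the external control RNA, which called 17, and 16 to 18 were called at 60 min. That centring weakened 76 gene calls and leaving out the dye term 40. Signal over background in the sample channel was 17.0 or more on every array. The number of arrays limits the precision, as does the dim reference channel on the standard arrays. Where an array was left out, its partner was taken to vary like the other groups. The cause of the changes below was not tested, unless stated.

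Counts are given for strain differences at 0, 15, 30, 60 and 90 min, for the interaction, and for the time courses, and counts not given stayed within 1.5 times. Without the dye term they were 4, 4, 27 and 47 up to 60 min, 4, 19 and 28 for the interaction at 30, 60 and 90 min, 116 in Hsf1-aa and 30 in WT-aa. Median centring gave 3 at 0 min (1 higher), 6 at 15 min (0 higher) and 53 in WT-aa. Print-tip loess gave 13 for the interaction at 30 min, and split the 8 at 0 min into 3 higher and 5 lower, as did the authors' values. Centring on the external control RNA gave 2, 2, 5, 25 and 24 (1 higher each time), 0, 6 and 13 for the interaction (0, 0 and 1 higher), 32 in Hsf1-aa (3 higher) and 0 in WT-aa. Equal scale gave 4 at 15 min (1 higher), 3 and 23 for the interaction at 30 and 60 min (0 and 7 higher) and 56 in WT-aa. The authors' values gave 18 for the interaction at 30 min, 465 in Hsf1-aa and 150 in WT-aa. A threshold of 1.7-fold, which removes calls by construction, left 3, 3, 17, 38 and 42, with 64 in Hsf1-aa and 17 in WT-aa. Array quality weights, which with 2 arrays per group weight groups and not arrays, gave 22 at 15 min, 19 at 30 min, 3 and 70 for the interaction at 30 and 60 min, 595 in Hsf1-aa and 1460 in WT-aa.

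From 0 to 90 min Hsf1-aa had 13 list calls at the preset correlation and 5 with an estimated one, and WT-aa had 14 and 7. With an estimated correlation 24 of the 68 list calls were kept. The targets at 15 min (-0.30) lost their call so, and those of WT-aa at 90 min (-0.14) did so and with fry (adjusted p = 0.166). The standard pair's target median was -1.815 (no background correction), -1.55 (median centring) and -1.73 (authors' values), and the correlation of slow with standard depletion was 0.336 without the targets.

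Centring on the external control RNA took the median of all genes, near 0 otherwise, to -0.173 for the strains at 0 min, -0.0729, -0.0536 and 0.0497 at 30, 60 and 90 min, 0.206 and 0.227 for the interaction at 15 and 90 min, -0.193 in Hsf1-aa at 30 min, and -0.302, -0.278, -0.197 and -0.231 in WT-aa from 15 to 90 min. With this common shift it reversed these medians: at 0 min general stress -0.076, Gcn4 -0.138, phosphate -0.094 and Yap1 -0.027; ribosome biogenesis -0.072 at 30 min and -0.040 at 60 min; at 90 min mitochondrial chaperones 0.014, ribosomal proteins 0.027 and glycolysis 0.025; and in WT-aa at 90 min general stress -0.124, respiration -0.222, G1/S -0.111, sulfur -0.077, Gcn4 -0.231, ergosterol -0.218, cell wall -0.144, MATalpha -0.042 and mating -0.054.

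Leaving out an array at a time gave 4 to 8, 4 to 16, 32 to 940, 44 to 143 and 58 to 81 for the strains, 0 to 1, 2 to 566, 24 to 62 and 32 to 48 for the interaction, 148 to 771 in Hsf1-aa, 38 to 1218 in WT-aa and 59 to 68 for lists. The 30 min arrays set the highest counts: without Hsf1-aa 30 min replicate b there were 940 at 30 min and 566 for the interaction, without its replicate a 771 in Hsf1-aa, without WT-aa 30 min replicate b 1218 in WT-aa. The lowest came without WT-aa 30 min replicate a (32), Hsf1-aa 60 min replicate a (44), Hsf1-aa 0 min replicate b (24 and 32), Hsf1-aa 0 min replicate a (4 at 0 min and 2), Hsf1-aa 15 min replicate b (4 at 15 min and 148) and WT-aa 90 min replicate b (38). Further counts that moved by over 1.5 times were, at 0 min, 4 without either WT-aa 0 min array and 5 without Hsf1-aa 0 min replicate b or an array of Hsf1-aa at 15 or 60 min or of WT-aa at 15, 30 or 90 min; at 15 min, 6 without Hsf1-aa 15 min replicate a, 8 without WT-aa 15 min replicate b or a WT-aa 60 min array and 9 without a WT-aa array of 0 or 90 min; 126 at 30 min without WT-aa 30 min replicate b; and at 60 min 143 without a Hsf1-aa 30 min array, 50 without Hsf1-aa 60 min replicate b, and 45 and 49 without WT-aa 60 min replicates a and b. For the interaction they were 1 at 15 min without WT-aa 15 min replicate b; at 30 min 3 without WT-aa 30 min replicate a and 4 without Hsf1-aa 0 min replicate b, Hsf1-aa 30 min replicate a, WT-aa 0 min replicate b or a WT-aa array of 15 or 90 min; and at 60 min 24 or 27 without any array of 0 min. Over time they were 672, 183 and 194 in Hsf1-aa without Hsf1-aa 30 min replicate b, 15 min replicate a and 60 min replicate a, 665 in WT-aa without a Hsf1-aa 30 min array, and 44 to 56 in WT-aa without WT-aa 15 min replicate b, 90 min replicate a or an array of WT-aa at 0 or 60 min. The target median of WT-aa at 90 min ranged from -0.1713 to -0.0895. Ergosterol genes at 0 min ranged from -0.131 to 0.016, reversed without Hsf1-aa 0 min replicate a.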

Other observations

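The hypothesis on brightness and timing below was chosen before its result was seen; the unnamed probes and the repeat without SSA1 were chosen after it.

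For 6 lists in WT-aa from 0 to 90 min, besides the Hsf1 chaperone targets, a call at the preset correlation was lost with an estimated one. No shift of these lists is claimed. HXK1, a hexokinase induced when glucose runs low, rose by 0.71 (adjusted p = 0.0157) as 1 of 30 general stress genes (2 adjusted over the list alone; median 0.10; adjusted p = 0.279 with an estimated correlation). CIT1, the mitochondrial citrate synthase, rose by 0.56 as 1 of 43 respiration genes (1 adjusted over the list alone; median 0.071; adjusted p = 0.279 with an estimated correlation). ERG25, a sterol methyl oxidase, rose by 0.54 as 1 of 23 genes of ergosterol synthesis (6 adjusted over the list alone; median 0.064; adjusted p = 0.129 with an estimated correlation). ARG3 rose by 0.32 as 1 of 29 Gcn4 genes (1 adjusted over the list alone; median 0.062; adjusted p = 0.169 with an estimated correlation). Cell wall integrity genes had a median of 0.16 with 0 of 12 past the threshold (0 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), and histone genes one of -0.064 with 0 of 10 (0 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation). Centring on the external control RNA turned the 5 positive medians to -0.124, -0.222, -0.218, -0.231 and -0.144, where the median of all genes was -0.231.

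Of the 8 features that differed before rapamycin, 3 were probes without a gene symbol. SCAB000951 was higher in Hsf1-aa at 1.81 ± 0.15 at 0 min and at 1.45 at 90 min. SCAB002074 was at -0.81 ± 0.07 and -1.19, and SCAB003230 at -0.53 ± 0.08 and -1.47. What these probes read is not given in the sources used here.

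Hsf1 chaperone targets had reached different shares of their 90 min strain difference by 30 min. SSA1 was at 14.5% and SIS1 at 17.8%, whereas BTN2 was at 58% and CPR6 at 62.5%. The shares do not subtract the 0 min difference, which ran from -0.30 (YDJ1) to 0.19 (SSA1), with CPR6 at -0.20. Whether the targets fell at different times was not tested. The hypothesis that targets with a brighter signal fell later was the only relation of this kind tested. Across the 18 targets, which are not independent replicates, mean intensity and the 30 min share gave Spearman rho = -0.542 (permutation p = 0.0222; Pearson r = -0.517). SSA1 had 2 spots near the scanner limit in the sample channel at 0 and 15 min, and 1 in the reference channel at 0 min. Without SSA1 rho was -0.456 (permutation p = 0.068). The brightness of different probes is not on a common scale either, so the hypothesis stays open.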
